A study of Homo sapiens with 12 samples.

How the data were processed

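The series holds RNA sequencing of HK-2, an immortalised line of human proximal tubule epithelial cells. The labels give 4 groups of 3 samples each, named after the short hairpin RNAs the cells carry. Luc976 was taken as the control hairpin because its name points to luciferase, a gene that human cells lack. The group shVHL61 carries a hairpin against VHL, shKIM1-A1 carries one against KIM-1 (gene HAVCR1), and shVHL61-KIM1A1 carries both. Per the labels' protocols, RNA was taken with Trizol and libraries were made from total RNA with an Illumina TruSeq RNA kit. The strand setting, the hairpin sequences and whether the 3 samples of a group came from separate cultures are not given in the sources used here. P-values therefore measure the spread between these samples, which may be technical.

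One table of the whole series was used, with 26506 genes named by symbol. Expected counts are estimated reads per gene that need not be whole, as deposited by the authors and per the file headers, and 89.7% to 90.7% of the values in a sample were whole numbers. TPM values were scaled by the authors within each sample, per the file headers, to the same total. FPKM values were also computed by the authors, per the file headers, and were used here only to work out each gene's effective length. The authors' deposited table further gives a fold, the linear ratio of each hairpin group over Luc976, and a value headed PPEE, which lies between 0 and 1 and carries the name the program EBSeq gives to a posterior probability of equal expression. Per the submitters' processing notes, Bowtie 0.12.2 and the builds mm8 and mm9 were named, with no role given. Both are mouse builds, while the gene names in the table are human. The human build, the annotation and the quantifier are not given in the sources used here, so no coordinates are printed.

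Expected counts were rounded to whole numbers. Depth ranged from 16500965 to 21089716 counts per sample, with 16565 to 16901 genes at 1 count or more and 5.87% to 6.55% of counts in the 10 most abundant genes. Genes with enough counts by filterByExpr of edgeR 4.0.16 (minimum count 10) were kept, which left 14230. Libraries were scaled by TMM, with factors from 0.976 to 1.05. Levels are given as CPM, counts per 1e6 counts, on TMM-scaled library sizes, as mean ± SD over the 3 samples of a group.

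One edgeR quasi-likelihood model was fitted to all 12 samples with the 4 groups as its terms, which leaves 8 residual degrees of freedom. The biological coefficient of variation was 6.8%. Tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene passed below 0.05. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of the F statistic. Comparisons were shVHL61 against Luc976, shKIM1-A1 against Luc976, shVHL61-KIM1A1 against each single hairpin and against Luc976, and the interaction, which is the effect of the KIM-1 hairpin with shVHL61 minus its effect without it. For OSM, with 2 or 3 counts in some groups, the ratio of summed counts is given with an exact 95% binomial interval, scaled by library size, which covers counting error only. The overlap of 2 comparisons was set beside the number given by independent lists, and for the pair that shares the Luc976 samples beside simulations of unchanged groups.

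The 19 gene lists fixed before the data were examined hold 536 symbols, of which 454 are among the tested genes. They cover HIF targets, glycolysis, HIF pathway regulators, oxidative phosphorylation, the IL-6/STAT3 response, NF-kB and inflammatory cytokines, the type I interferon response, tubular injury, proximal tubule identity, other nephron segments, fibroblast, endothelial and immune markers, epithelial markers, mesenchymal and matrix genes, cell cycle, p53 targets, unfolded protein and amino acid stress, cholesterol and fatty acid synthesis, the NRF2 antioxidant response, and lysosome and phagocytosis. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and adjusted over the 19 lists of a comparison. Where a call was lost with the correlation estimated from the residuals, that adjusted p is given beside it. Members are counted as risen or fallen by their p adjusted over all genes and, separately, adjusted over the list alone.

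The genes named in the text follow a rule that was also set before the data were examined. It takes VHL and HAVCR1 in every comparison. For shVHL61 and shKIM1-A1 against Luc976 and for shVHL61-KIM1A1 against shVHL61 it takes the 8 largest rises and 8 largest falls, and for the other comparisons 4 each. These come from protein-coding-looking symbols past the threshold, with an average log2 CPM of at least 2 and no overlap between the samples of the 2 groups (a condition not used for the interaction). From each list it takes up to 4 members with the smallest p among those past the threshold, and HIF pathway regulators whatever their result. Some named members of lists were left out because 1 omitted sample or 1 other setting ended their call, and some others are not used here. MT1L, SFTA1P, SAA2, FER1L4, IFITM1, IFITM2, IFITM3 and RTEL1-TNFRSF6B share sequence or reads with near copies or overlapping genes, so their values are uncertain.

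Replicate pairs were compared by a chi-square test on genes with at least 20 counts. The statistic per gene ran from 1.86 to 12.05, so no pair lay within sampling noise, and the correlation of log2 CPM was 0.9908 to 0.9935. In each group 2 samples lay close and the other stood apart. A grouping by the sign of each library's correlation with transcript GC content, defined after the data were examined, gave 2 sets of 6 libraries that follow these pairs. Set A holds Luc976 samples 1 and 3, shVHL61 sample 1, shKIM1-A1 sample 2 and shVHL61-KIM1A1 samples 2 and 3, and set B holds the others. Every group is present in both sets, and each count of genes is also given within each set, where 2 residual degrees of freedom remain and lone samples are assumed to vary like the rest. The sets are spread unevenly: Luc976 and shVHL61-KIM1A1 lie mostly in set A, and shVHL61 and shKIM1-A1 mostly in set B. A difference between the sets therefore enters the interaction and every comparison except shVHL61-KIM1A1 against Luc976. Replicate numbers did not pair the samples.

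Alternatives planned before the data were examined were the size factors of DESeq2 in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, only the groups compared in the fit, the replicate number as a block, omission of each sample in turn, and, for lists, an estimated correlation and the fry test. Alternatives added after the data were examined were removal of a smooth trend on gene length, or on gene length and transcript GC content, in each library (mgcv 1.9.3, entered as offsets), limma on log2(TPM + 1) for genes with a TPM of at least 1 in at least 3 samples, the library set as a term, and fits within each set. Effective length was known for 87.6% of the tested genes and GC content for 97.6%.

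The procedure was tested on simulated counts for 14077 genes with known changes. For shVHL61 against Luc976, 65% of genes changed by a log2 of 0.5 and 89% of those changed by 1 were called, and 5.52% of calls were false. For the interaction the shares were 40% and 85%, with 8.76% of calls false. Simulated shKIM1-A1 samples with no change gave 1 call. A shift put into the HIF target list gave 0 passing tests among the other 18 lists. The simulated genes varied independently and without library sets, so this check cannot judge the preset correlation. R 4.3.3, python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.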

Results

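The series measured mRNA in HK-2 cells that carry a control hairpin (Luc976), a hairpin against VHL (shVHL61), a hairpin against KIM-1 (shKIM1-A1) or both (shVHL61-KIM1A1), with 3 samples each. VHL is the substrate-recognition part of the ubiquitin ligase that marks hypoxia-inducible factors (HIF) for breakdown. KIM-1, the product of HAVCR1, is a membrane receptor of injured proximal tubule cells that takes up dead cells and lipids. The design asks what each knockdown changes alone and what the KIM-1 knockdown changes in cells that also carry the VHL hairpin. Each sample held 16500965 to 21089716 counts. The first principal component of log2 CPM took 41.2% of the variance and set the shVHL61-KIM1A1 samples (scores 42.2 to 43.7) apart from all others (-26.2 to -1.2). The second took 21.2% and set shKIM1-A1 (-28.5 to -28.2) apart from shVHL61 (21.6 to 22.5).

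VHL mRNA stood at 53.2 ± 0.376 CPM in Luc976, 38.1 ± 1.07 in shVHL61, 59.5 ± 1.88 in shKIM1-A1 and 41.6 ± 2.92 in shVHL61-KIM1A1 cells (SD, n = 3 each). Against Luc976 it fell to 0.716 of the control level in shVHL61 cells (log2 fold change -0.48, SE 0.07, edgeR adjusted p = 9.17e-05) and to 0.782 in shVHL61-KIM1A1 cells (-0.36, adjusted p = 0.000272). In shKIM1-A1 cells VHL differed from Luc976 by 0.16 (adjusted p = 0.0679). HAVCR1 stood at 121 ± 10.8 CPM in Luc976, 143 ± 10.4 in shVHL61, 57.0 ± 4.45 in shKIM1-A1 and 83.7 ± 14.1 in shVHL61-KIM1A1 cells. It fell to 0.472 of the control level in shKIM1-A1 cells (log2 fold change -1.08, SE 0.10, adjusted p = 1.23e-06) and to 0.693 in shVHL61-KIM1A1 cells (-0.53, adjusted p = 0.000381). Between the lines with the KIM-1 hairpin, HAVCR1 was higher where shVHL61 was also present (log2 0.55, adjusted p = 0.000437). Within library sets A and B, VHL in shVHL61 against Luc976 gave -0.43 and -0.51, and HAVCR1 in shKIM1-A1 against Luc976 gave -1.13 and -1.16.

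**Figure D1:**
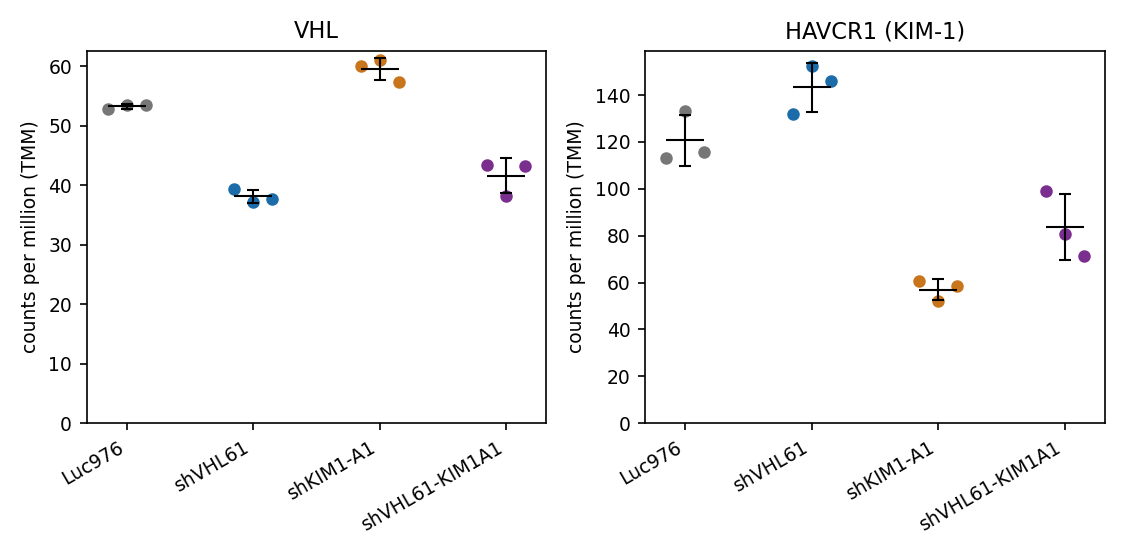
Levels (CPM, TMM-scaled) of VHL and HAVCR1 in each sample by group, with bars at the mean ± SD of 3 samples. VHL averaged 38.1 and 41.6 in the groups that carry shVHL61, against 53.2 and 59.5 in the others.

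In shVHL61 cells the mRNA of oncostatin M (OSM), a cytokine of the IL-6 family, stood at 8.46 ± 0.807 CPM against 0.0374 ± 0.0325 CPM in Luc976 (SD, n = 3 each). The 3 libraries of each group held 507 and 2 OSM counts, a ratio of 235 with a 95% counting interval of 64.8 to 1950. COL5A1, a fibrillar collagen, fell by 2.51 on the log2 scale (59.2 ± 6.88 to 10.4 ± 1.23 CPM, edgeR adjusted p = 5.2e-10), EFEMP1 (fibulin-3) by 2.24, THBS1 (thrombospondin-1) by 2.04, the glypican GPC4 by 1.76, VWA1 by 1.70 and COL11A1 by 1.59, with SE from 0.09 to 0.14. CLDN2, the cation-pore claudin of the proximal tubule, fell by 1.86 (213 ± 7.93 to 58.5 ± 1.05 CPM), and CDKN1C, a cyclin-dependent kinase inhibitor, fell by 1.82. Among the largest rises were CDKN1A, the p21 inhibitor of cyclin-dependent kinases (log2 1.44, SE 0.09), TMX3 of the endoplasmic reticulum (1.59, SE 0.15), the tight junction protein OCLN (1.34), the sulfotransferase SULT1C2 (1.33) and the Wnt enhancer RSPO3 (1.30). MT1L (1.43) and SFTA1P (1.34) also rose, with reads that near copies can share.

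HIF targets did not rise as a group in shVHL61 cells. Of 35 measured members 1 rose and 8 fell, with the same counts adjusted over the list alone, and camera gave an adjusted p of 0.167. The fry test called the list lower (adjusted p = 0.00104). CA9, a carbonic anhydrase used as a marker of HIF activity, fell by 1.55 (SE 0.15, 6.08 ± 0.295 to 2.07 ± 0.376 CPM), while the glucose transporter SLC2A3 rose by 0.69. CA12 fell by 0.43. Among 13 measured HIF pathway regulators, EPAS1 (HIF-2 alpha) rose by 0.22 (SE 0.05, adjusted p = 0.00786) and ARNT2 fell by 1.66 (SE 0.18), whereas HIF1A differed by 0.16 (adjusted p = 0.208), EGLN1 by 0.06 and EGLN3 by -0.01. That list held 1 rise and 3 falls (1 and 3 adjusted over the list alone, list adjusted p = 0.428). VHL, the target of the hairpin, is a member and is among the falls.

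Cholesterol and fatty acid synthesis passed the threshold in shVHL61 cells, where 0 of 30 members rose and 11 fell (1 and 11 adjusted over the list alone, adjusted p = 0.0256). Its adjusted p was 0.125 with an estimated correlation. It was 0.0704 with the gene length trend removed, with a median of -0.10 against -0.09, but 0.00592 with length and GC trends removed and 0.000242 with the library set as a term. The fatty acid elongase ELOVL6 fell by 0.39, the regulator SREBF2 by 0.33 and the sterol enzyme LSS by 0.37. In the list of NF-kB and inflammatory cytokines 6 of 22 members rose and 1 fell (6 and 1 adjusted over the list alone, list adjusted p = 0.0565). The library sets are spread unevenly over these groups, and with the set as a term this list passed (adjusted p = 0.00654), as did the NRF2 list (0.0257, against 0.105 without it). With length and GC trends removed the adjusted p was 0.00592 for NF-kB and 0.0788 for NRF2. In the main fit with an estimated correlation it was 0.329 for NF-kB and 0.362 for NRF2. CXCL8, encoding interleukin-8, rose by 0.93, BIRC3 by 0.84 and CSF1 by 0.44, and CXCL5 fell by 1.12. The matrix list had 6 rises and 11 falls of 32 (9 and 12 adjusted over the list alone, adjusted p = 0.0752), with FBN1 down by 1.35. Of 27 IL-6/STAT3 response genes 2 rose and 4 fell (2 and 5 adjusted over the list alone, adjusted p = 0.493): IL6 rose by 0.58, and IL11 fell by 1.08. Tubular injury genes went both ways (7 rose and 7 fell of 21, 8 and 8 adjusted over the list alone), with PLAU (urokinase) up by 1.11 and SOX9 down by 1.29.

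In all, 2374 of 14230 genes passed for shVHL61 against Luc976, 1024 higher and 1350 lower, and 302 changed at least 2-fold. The higher share was 43.1%, against 29.1% with limma on log2(TPM + 1), 49.3% with length and GC trends removed and 51.2% with only these 2 groups in the fit. Within library sets A and B, 2180 and 2470 genes passed, and the fold changes of all genes correlated with r = 0.428 between the sets. Omitting 1 sample lowered the count to 1384 (Luc976 sample 1), 1328 (Luc976 sample 3), 1329 (shVHL61 sample 2) or 1343 (shVHL61 sample 3). The count was 3991 with length and GC trends removed and 4117 with the library set as a term. Across genes the fold changes correlated with transcript GC content (Spearman -0.362), by which the library sets were defined. Luc976 lies mostly in set A and shVHL61 mostly in set B.

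**Figure D2:**
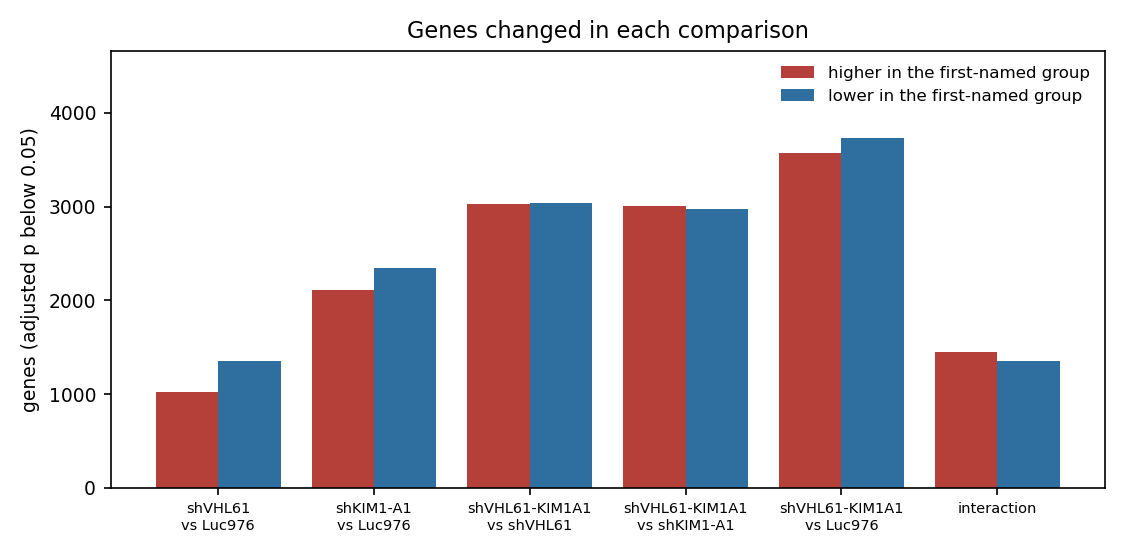
Number of genes past an edgeR adjusted p of 0.05 in each comparison, split by direction. Counts run from 1024 higher and 1350 lower (shVHL61 against Luc976) to 3575 higher and 3730 lower (shVHL61-KIM1A1 against Luc976).

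With the KIM-1 hairpin alone, HIF targets and p53 targets rose and genes of cholesterol synthesis fell. Of 35 HIF targets 18 rose and 5 fell (21 and 5 adjusted over the list alone, camera adjusted p = 0.000393), among them the mitophagy receptor BNIP3 (log2 0.54, SE 0.06), the collagen hydroxylase P4HA1 (0.66) and PFKFB4 (0.55), while STC2 fell by 0.55. Of 24 p53 targets 11 rose and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.00069). CDKN1A rose 3.89-fold, from 26.3 ± 2.80 to 102 ± 9.24 CPM (SD, n = 3 each, edgeR adjusted p = 2.34e-10), TP53INP1 by 0.98, the repair gene DDB2 by 0.64 and SESN2 by 0.52. Of 30 cholesterol and fatty acid synthesis genes 1 rose and 16 fell (1 and 16 adjusted over the list alone, adjusted p = 3.94e-05). The sterol enzyme LSS fell by 0.67 and squalene epoxidase SQLE by 0.40. These 3 lists also passed with an estimated correlation (adjusted p = 0.0251, 0.0251 and 0.0124).

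Lymphotoxin beta (LTB) had the largest rise of the named genes in shKIM1-A1 cells, 6.26-fold (3.60 ± 0.0254 to 22.6 ± 3.00 CPM, adjusted p = 4.99e-10). IL23A, a subunit of interleukin-23, rose by 1.93 on the log2 scale, the antimicrobial peptide DEFB1 by 1.64, the pro-apoptotic BMF by 1.48, PRKCB by 1.46 and TMX3 by 1.45. The small GTPase RRAD rose 2.83-fold. INHBB, the beta B subunit of activin, fell by 2.77 (SE 0.23, 5.21 ± 0.626 to 0.765 ± 0.408 CPM). THBS2 fell by 1.83, the proteoglycan BGN by 1.81, the protease ADAMTS15 by 1.91, the phosphatase DUSP9 by 1.78 and the matrix protease MMP7 by 1.70. IFITM2 (-2.31) and RTEL1-TNFRSF6B (-1.69) also fell, with reads that near copies or overlapping genes can share.

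In shKIM1-A1 cells 5 further lists passed camera with the preset correlation but not with the estimated correlation. NF-kB and inflammatory cytokines were higher (12 rose and 2 fell of 22, 13 and 2 adjusted over the list alone, adjusted p = 0.00404, but adjusted p = 0.0724 with an estimated correlation). Its members NFKBIA (0.66), TNFAIP2 (0.61) and CXCL8 (0.86) rose, and the mitochondrial superoxide dismutase SOD2 fell by 1.13. Tubular injury genes were lower (2 rose and 9 fell of 21, 4 and 9 adjusted over the list alone, adjusted p = 0.0172, and adjusted p = 0.23 with an estimated correlation). HAVCR1, the target of the hairpin, is a member, MMP7 fell by 1.70 and CTGF by 0.99, and PLAU rose by 0.57. IL-6/STAT3 response genes were lower (4 rose and 10 fell of 27, 4 and 10 adjusted over the list alone, adjusted p = 0.0281, and adjusted p = 0.265 with an estimated correlation). IL6 itself rose by 1.16, while the receptor LIFR fell by 1.16, IL11 by 1.03 and the kinase PIM1 by 0.66. The NRF2 list was lower (3 rose and 11 fell of 23, 3 and 12 adjusted over the list alone, adjusted p = 0.0291, and adjusted p = 0.256 with an estimated correlation), with falls of 0.49 in NQO1, 0.33 in PGD and 1.29 in the transporter ABCC2. Mesenchymal and matrix genes were lower (7 rose and 13 fell of 32, 8 and 15 adjusted over the list alone, adjusted p = 0.0476, and adjusted p = 0.265 with an estimated correlation). TGFBI fell by 0.82 and COL4A1 by 0.69, and TGFBR1 rose by 1.17 and ITGB3 by 0.64. With length and GC trends removed, the adjusted p was 0.0959 for tubular injury (median -0.16 before and -0.13 after), 0.0524 for IL-6/STAT3 (-0.10 and -0.12), 0.0953 for NRF2 (-0.18 and -0.15) and 0.0522 for the matrix list (-0.19 and -0.22). These 4 lists passed with the length trend alone removed.

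Proximal tubule identity genes in shKIM1-A1 cells had 5 rises and 0 falls among 17 (5 and 0 adjusted over the list alone, adjusted p = 0.296), including the inositol oxygenase MIOX (1.04), GATM (0.78) and MME (0.73), but their median was -0.08 and their mean 0.09. Of 29 interferon response genes 9 rose and 3 fell (9 and 3 adjusted over the list alone, adjusted p = 0.244), with IFI44L down by 1.46. Epithelial markers were mixed (4 rose and 7 fell of 21, 6 and 8 adjusted over the list alone, adjusted p = 0.788), with EPCAM up by 0.84 and the desmosome gene DSP down by 0.77. In all, 4456 genes passed, 2109 higher and 2347 lower, and 385 changed at least 2-fold. The higher share was 47.3%, against 68.2% with limma on log2(TPM + 1). Within library sets A and B the counts were 3986 and 4747, and the fold changes of all genes correlated with r = 0.573 between the sets.

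When the KIM-1 hairpin was added to shVHL61, HIF targets rose as a group. Of 35 members 30 rose and 2 fell (31 and 3 adjusted over the list alone), with a median log2 fold change of 0.60, camera adjusted p = 4.54e-15, and adjusted p = 0.000815 with an estimated correlation. CA9 rose 6.02-fold, from 2.07 ± 0.376 in shVHL61 to 12.5 ± 0.249 CPM in shVHL61-KIM1A1 cells (SD, n = 3 each, edgeR adjusted p = 1.66e-09). NDRG1, a hypoxia-induced gene, rose 2.57-fold (69.6 ± 1.30 to 179 ± 5.31 CPM), PFKFB4 2.33-fold and BNIP3 2.32-fold. VHL itself did not pass between these lines (log2 0.13, SE 0.07, 95% interval -0.03 to 0.28, adjusted p = 0.137). HAVCR1 changed between them by a log2 of -0.80 in library set A and -0.59 in set B. The list median was 0.68 in library set A and 0.63 in set B.

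**Figure D3:**
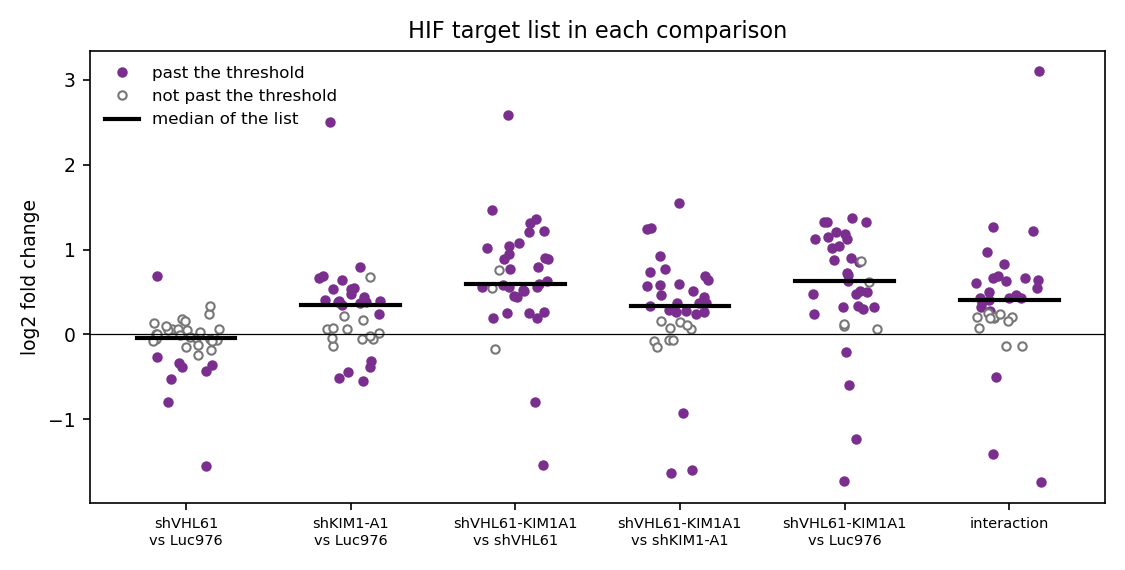
Log2 fold change of each of the 35 measured HIF targets in each comparison, with a bar at the list median. The median was -0.04 in shVHL61 against Luc976, 0.35 in shKIM1-A1 against Luc976 and 0.60 in shVHL61-KIM1A1 against shVHL61.

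The prolyl hydroxylase EGLN3, itself induced by HIF, rose by 0.89 in shVHL61-KIM1A1 over shVHL61 cells, and the coactivators CREBBP and EP300 fell by 0.69 and 0.51. The HIF regulator list had 4 rises and 3 falls of 13 (4 and 3 adjusted over the list alone, adjusted p = 0.666). Of 21 glycolysis genes 15 rose and 0 fell (16 and 1 adjusted over the list alone, adjusted p = 7.92e-06, but adjusted p = 0.203 with an estimated correlation). ENO2 rose by 1.02, the branching enzyme GBE1 by 0.83, PGK1 by 0.72 and PGM1 by 0.56. Of 28 genes of unfolded protein and amino acid stress 16 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 4.5e-05, and adjusted p = 0.0292 with an estimated correlation). They included asparagine synthetase ASNS (1.06), the transcription factor ATF3 (1.12), the chaperone HSPA5 (0.53) and PDIA6 (0.37). Of 24 p53 targets 12 rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 0.00283, and adjusted p = 0.0361 with an estimated correlation), with TP53INP1 up by 1.26, BTG2 by 1.10, DDB2 by 1.01 and CDKN1A by 0.76.

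Oxidative phosphorylation genes had 14 rises and 1 fall of 29 in this comparison (14 and 1 adjusted over the list alone, adjusted p = 0.00061). Their adjusted p was 0.3 with an estimated correlation and 0.399 after the gene length trend was removed (median 0.17 before and 0.07 after), and NDUFB5 (0.50), NDUFA4 (0.37) and NDUFA9 (0.32) were among them. The interferon list had 13 rises and 3 falls of 29 (13 and 4 adjusted over the list alone, adjusted p = 0.0393, but adjusted p = 0.118 with an estimated correlation and 0.0675 with the length trend removed, median 0.23 before and 0.20 after). IFI6 rose by 0.63 and IFITM1 by 0.96, and IFI44L fell by 0.69. Of 40 cell cycle genes 5 rose and 16 fell (5 and 17 adjusted over the list alone, adjusted p = 0.0393, but adjusted p = 0.179 with an estimated correlation), with the phosphatase CDC25A down by 0.66, the proliferation marker MKI67 by 0.55, FOXM1 by 0.45 and RRM2 by 0.43. Of 21 epithelial markers 7 rose and 5 fell (7 and 5 adjusted over the list alone, adjusted p = 0.371), and E-cadherin (CDH1) rose by 1.18, CLDN4 by 0.84 and EPCAM by 0.89.

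Among genes with an average log2 CPM of at least 2, large rises beside CA9 were in MAP1LC3C, an LC3 protein of autophagy (2.43), DEFB1 (2.18), PPFIA4 (1.92), BMF (1.84) and the membrane proteolipid MAL (1.78), with FER1L4 (1.91) and SAA2 (1.74) less certain because of near copies. Large falls at that level of expression were in GPC4 (log2 -3.80, 3.26 ± 0.266 to 0.227 ± 0.103 CPM), fibulin-2 (FBLN2, -3.24), the adaptor SHC3 (-3.07), fibrillin (FBN1, -2.68), the drug pump ABCB1 (-2.63), FUT9 (-2.22), KIF26B (-2.15) and apolipoprotein E (APOE, -2.15), all with edgeR adjusted p of at most 1.11e-06. In all, 6059 genes passed, 3025 higher and 3034 lower, and 678 changed at least 2-fold. The higher share was 49.9%, against 39.4% with limma on log2(TPM + 1). The counts were 6254 in library set A and 5579 in set B, with r = 0.564 between the fold changes of all genes. Genes that were higher with both hairpins tended to be short (Spearman -0.284 of fold change with length, across genes, which are not independent replicates).

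When shVHL61 was added to the KIM-1 hairpin, OSM again appeared: 13.6 ± 2.09 CPM in shVHL61-KIM1A1 against 0.0527 ± 0.0527 in shKIM1-A1 cells (SD, n = 3 each). The counts were 716 and 3, a ratio of 265 with a 95% counting interval of 90.3 to 1290. INHBB rose 50.5-fold, from 0.765 ± 0.408 to 38.5 ± 1.98 CPM (edgeR adjusted p = 7.74e-13), MAP1LC3C 9.22-fold and cytidine deaminase CDA 8.44-fold (3.65 ± 0.0308 to 30.9 ± 1.60 CPM). Large falls among genes with an average log2 CPM of at least 2 were in GPC4 (log2 -4.79), FBN1 (-4.15), SHC3 (-3.86) and COL5A1 (-3.78). HIF targets rose (23 rose and 3 fell of 35, 23 and 4 adjusted over the list alone, camera adjusted p = 3.01e-06, and adjusted p = 0.0189 with an estimated correlation). EGLN3 rose by 1.26, the peptide hormone ADM by 1.24 and NDRG1 by 0.93, and CA12 fell by 0.93.

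Among HIF pathway regulators in this comparison 6 rose and 6 fell of 13 (6 and 6 adjusted over the list alone, adjusted p = 0.856). VHL, the target of the added hairpin, is a member. HIF1A rose by 0.46 and EPAS1 by 0.51, and ARNT2 fell by 1.60, CREBBP by 0.55, EGLN2 by 0.37 and the asparaginyl hydroxylase HIF1AN by 0.35. Proximal tubule identity genes were lower (0 rose and 8 fell of 17, 0 and 8 adjusted over the list alone, adjusted p = 0.00482, but adjusted p = 0.0586 with an estimated correlation), with MME down by 2.09, GATM by 1.43 and MIOX by 0.90. Unfolded protein and amino acid stress genes were higher (13 rose and 1 fell of 28, 13 and 1 adjusted over the list alone, adjusted p = 0.000432, but adjusted p = 0.0586 with an estimated correlation), including ASNS (0.71), HSP90B1 (0.57), HSPA5 (0.40) and PDIA6 (0.40). Of 21 glycolysis genes 14 rose and 1 fell (14 and 2 adjusted over the list alone, adjusted p = 0.00015, but adjusted p = 0.299 with an estimated correlation), with SLC2A3 up by 0.77, PGK1 by 0.64 and LDHA by 0.50.

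With the preset but not the estimated correlation in camera, 3 more lists were higher in shVHL61-KIM1A1 than in shKIM1-A1 cells. Oxidative phosphorylation had 19 rises and 0 falls of 29 (21 and 0 adjusted over the list alone, adjusted p = 3.01e-06, and adjusted p = 0.184 with an estimated correlation), among them UQCRC2 (0.52) and SDHB (0.50). With the gene length trend removed its adjusted p was 0.129 and its median went from 0.28 to 0.09. The NRF2 list had 11 rises and 1 fall of 23 (12 and 1 adjusted over the list alone, adjusted p = 0.00893, and adjusted p = 0.184 with an estimated correlation or 0.0805 with the length trend removed, median 0.21 before and 0.11 after), with ferritin FTH1 up by 0.69, and NQO1 and TXN by 0.48 each. Lysosome and phagocytosis genes had 10 rises and 2 falls of 29 (10 and 2 adjusted over the list alone, adjusted p = 0.0479, and adjusted p = 0.299 with an estimated correlation or 0.129 with the length trend removed). CTSB rose by 0.80 and NPC2 by 0.50. The median of this list was 0.10, 0.13 with the length trend removed and -0.07 on the log2(TPM + 1) scale, where the median of all genes shifted by -0.153. Markers of other nephron segments had 1 rise and 3 falls of 5 (1 and 3 adjusted over the list alone, adjusted p = 0.333), with the sodium channel subunit SCNN1A up by 0.40 and PODXL down by 0.50. In all, 5975 genes passed, 3002 higher and 2973 lower, 876 of them at least 2-fold. The higher share was 50.2%, against 20% with limma on log2(TPM + 1). Within library sets A and B the counts were 6450 and 5580, with r = 0.733 between the fold changes of all genes, and the correlation of fold change with gene length across genes was -0.328.

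Against Luc976, cells with both hairpins had 716 OSM counts against 2, a ratio of 379 with a 95% counting interval of 104 to 3130. MAP1LC3C rose 9.66-fold, INHBB 7.40-fold (5.21 ± 0.626 to 38.5 ± 1.98 CPM, SD, n = 3 each) and DEFB1 6.59-fold. Matrix genes were among the large falls at an average log2 CPM of at least 2: GPC4 fell by 5.55 on the log2 scale, FBLN2 by 4.65, COL5A1 by 4.36 and FBN1 by 4.03, with edgeR adjusted p of at most 3.63e-12. Mesenchymal and matrix genes had 6 rises and 19 falls of 32 (6 and 19 adjusted over the list alone, adjusted p = 0.00848). Their adjusted p was 0.146 with an estimated correlation and 0.0613 with the gene length trend removed (median -0.43 before and -0.33 after). HIF targets had 26 rises and 4 falls of 35 (27 and 4 adjusted over the list alone, adjusted p = 2.74e-09, and adjusted p = 0.0044 with an estimated correlation), with NDRG1 up 2.49-fold, SLC2A3 2.31-fold and BNIP3 2.26-fold.

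The other lists past the threshold against Luc976 were lost with an estimated correlation. Those that were higher were glycolysis (12 rose and 2 fell, adjusted p = 0.293 with an estimated correlation), oxidative phosphorylation (14 and 1, adjusted p = 0.272), NF-kB and inflammatory cytokines (9 and 3, adjusted p = 0.146), the interferon response (13 and 0, adjusted p = 0.0509), p53 targets (14 and 3, adjusted p = 0.0509) and unfolded protein and amino acid stress (15 and 3, adjusted p = 0.0509). Adjusted over the list alone, the counts were 12 and 2, 15 and 1, 9 and 3, 12 and 0, 14 and 3, and 16 and 3. Those that were lower were proximal tubule identity (1 rose and 9 fell, 1 and 9 adjusted over the list alone, adjusted p = 0.145 with an estimated correlation) and cholesterol synthesis (5 and 14, 6 and 14 adjusted over the list alone, adjusted p = 0.0705). CDKN1A rose 4.60-fold, CXCL8 3.23-fold, ASNS 2.36-fold and BTG2 2.29-fold, and ELOVL6 fell to 0.51 of its Luc976 level. With the length trend removed, the adjusted p (preset correlation) was 0.44 for oxidative phosphorylation (median 0.20 before and 0.03 after), 0.118 for NF-kB (0.13 and 0.12), 0.0613 for proximal tubule identity (-0.33 both times) and 0.0801 for cholesterol synthesis (-0.16 and -0.17). With length and GC trends removed, NF-kB and cholesterol synthesis passed (adjusted p = 0.0499 each). Fibroblast, endothelial and immune markers did not pass (3 rose and 2 fell of 8, 3 and 2 adjusted over the list alone, adjusted p = 0.654), and their median of 0.20 and mean of -0.52 differed in sign. Decorin (DCN) fell from 6.60 ± 0.803 to 0.0956 ± 0.0341 CPM, the endothelial cadherin CDH5 rose from 0.769 ± 0.172 to 2.51 ± 0.304 CPM, and CD68 rose by 0.40. In all, 7305 genes passed, 3575 higher and 3730 lower, 1008 of them at least 2-fold. The higher share was 48.9%, against 37.0% with limma on log2(TPM + 1). In library set A 8213 genes passed and in set B 5932, with r = 0.755 between the fold changes of all genes, and the correlation of fold change with gene length across genes was -0.22.

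The interaction asked whether the KIM-1 hairpin acted differently with and without shVHL61. Among genes with an average log2 CPM of at least 2, INHBB had a large positive value, a log2 of 4.38 (SE 0.25, edgeR adjusted p = 1.04e-08): it fell by 2.77 with the KIM-1 hairpin alone, and it stood at 12.6 ± 0.663 CPM in shVHL61 and 38.5 ± 1.98 CPM in shVHL61-KIM1A1 cells. CA9 had 3.10 (SE 0.20), IFITM2 2.54 and CDA 2.43. Negative values at that level of expression included SHC3 (-3.91, SE 0.26, adjusted p = 6.55e-08), GPC4 (-3.03), FBN1 (-2.80) and FUT9 (-2.56). FBN1 stood at 52.2 ± 2.36 CPM in Luc976, 20.5 ± 0.849 in shVHL61, 56.8 ± 3.93 in shKIM1-A1 and 3.22 ± 0.794 in shVHL61-KIM1A1 cells (SD, n = 3 each). The interaction did not pass for VHL (-0.03, adjusted p = 0.848) or HAVCR1 (0.31, adjusted p = 0.15).

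**Figure D4:**
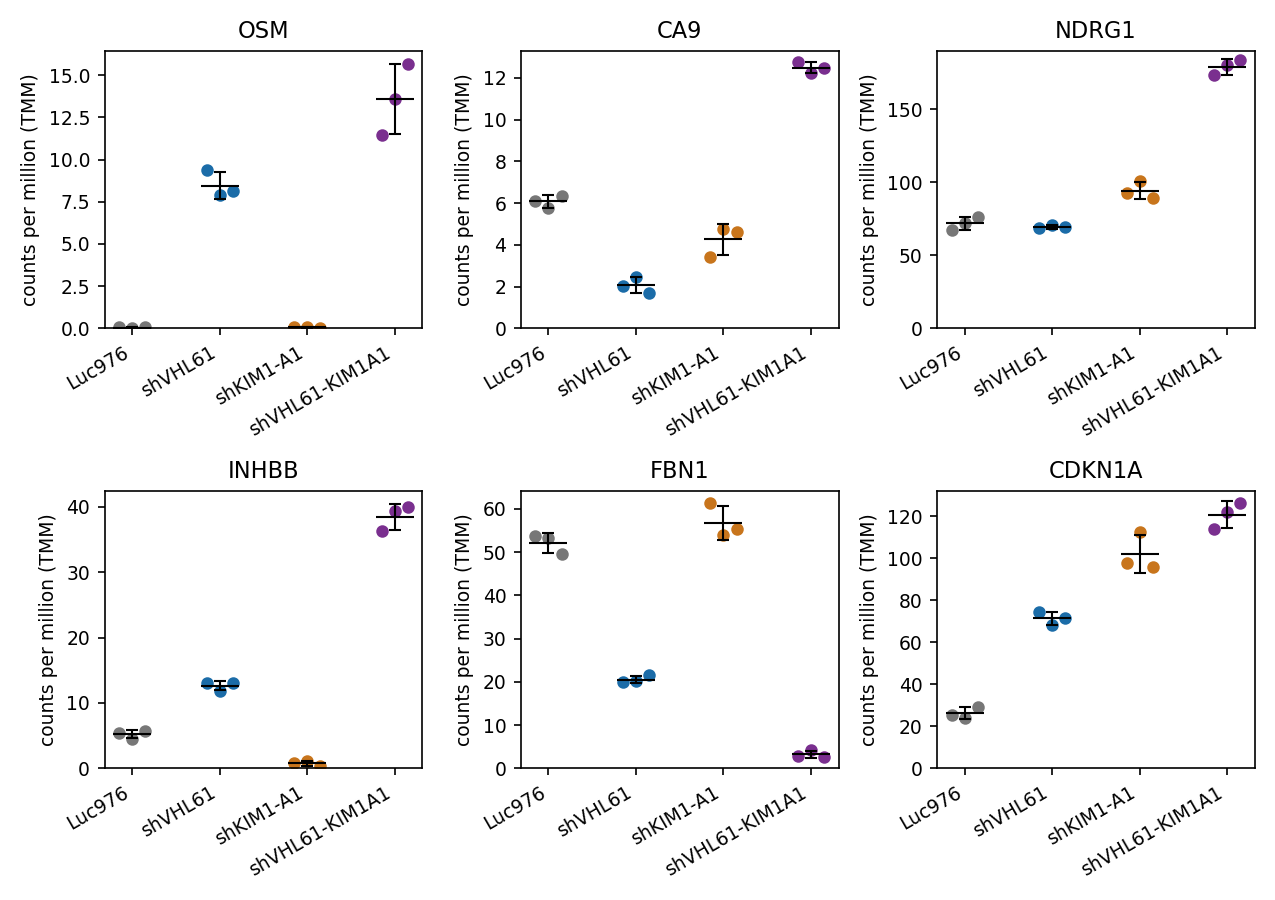
Levels (CPM, TMM-scaled) of 6 genes in each sample by group, with bars at the mean ± SD of 3 samples. CA9 averaged 12.5 with both hairpins, against 6.08 in Luc976, 2.07 in shVHL61 and 4.26 in shKIM1-A1 cells.

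HIF targets had 21 positive and 3 negative interactions of 35 (22 and 3 adjusted over the list alone), with a median of 0.41, camera adjusted p = 1.8e-09, and adjusted p = 0.00409 with an estimated correlation. EGLN3 (1.27), ADM (1.22) and NDRG1 (0.97) were among them, and the median was 0.44 in library set A and 0.37 in set B. Unfolded protein and amino acid stress genes had 13 positive and 1 negative of 28 (15 and 1 adjusted over the list alone, adjusted p = 3.6e-05, and adjusted p = 0.0298 with an estimated correlation), with ATF3 at 1.36 and ASNS at 0.54. Proximal tubule identity genes had 0 positive and 6 negative of 17 (1 and 6 adjusted over the list alone, adjusted p = 0.00435, and adjusted p = 0.0456 with an estimated correlation), with MME at -1.51, GATM at -1.27 and MIOX at -1.22. Cholesterol and fatty acid synthesis genes had 9 positive and 1 negative of 30 (9 and 2 adjusted over the list alone, adjusted p = 0.00837, and adjusted p = 0.0456 with an estimated correlation), with FDFT1 at 0.56 and INSIG1 at 0.50. The median of that list was 0.12, and -0.03 on the log2(TPM + 1) scale, where the median of all genes shifted by -0.135.

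For the interaction 5 lists passed camera with the preset correlation but not with the estimated correlation. They were glycolysis (9 positive and 0 negative of 21, 10 and 0 adjusted over the list alone, adjusted p = 0.196 with an estimated correlation), oxidative phosphorylation (10 and 0 of 29, 13 and 0 adjusted over the list alone, adjusted p = 0.196), the IL-6/STAT3 response (9 and 3 of 27, 10 and 4 adjusted over the list alone, adjusted p = 0.229), cell cycle (1 and 8 of 40, 1 and 8 adjusted over the list alone, adjusted p = 0.196) and lysosome and phagocytosis (8 and 1 of 29, 9 and 1 adjusted over the list alone, adjusted p = 0.229). With the length trend removed, the adjusted p was 0.171 for oxidative phosphorylation (median 0.22 before and 0.06 after) and 0.147 for the lysosome list (0.11 and 0.10), whose median was -0.05 on the log2(TPM + 1) scale. PGK1 stood at 0.62, CEBPD at 0.93, PIM1 at 0.81, IL6 at -0.80, MKI67 at -0.62 and CTSB at 0.59. CDKN1A, which rose in each hairpin group against Luc976, had a negative interaction of -1.20. In all, 2800 genes passed, 1450 positive and 1350 negative. The positive share was 51.8%, against 24.0% with limma on log2(TPM + 1). Within library sets A and B the counts were 3248 and 2833, with r = 0.428 between the interactions of all genes, and the correlation of the interaction with gene length across genes was -0.374. The count was 2476 with the length trend removed (2032 of the 2800 among them), 4392 with length and GC trends removed and 4799 with the library set as a term.

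**Figure D5:**
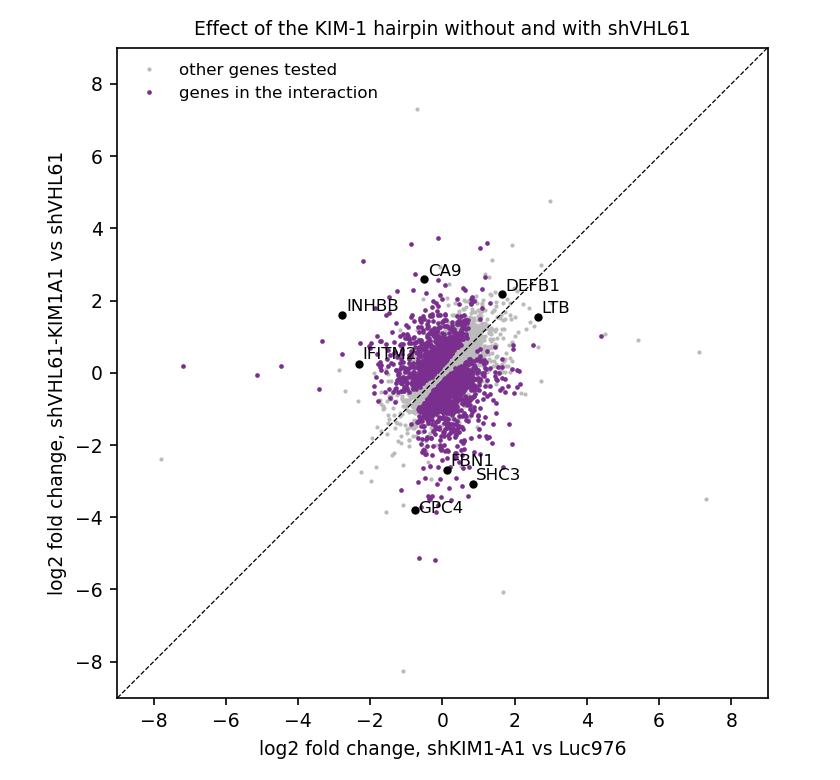
Log2 fold change of each tested gene for the KIM-1 hairpin without (x axis) and with (y axis) shVHL61, with the 2800 genes of the interaction in colour and a dashed line of equal change. INHBB, CA9 and IFITM2 lie above the line, and FBN1, SHC3 and GPC4 lie below it.

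Genes called for shVHL61 against Luc976 and again for shVHL61-KIM1A1 against shKIM1-A1, which share no library, numbered 1338 with the same sign (521 higher, 817 lower), where independent lists would give 216 and 282, and 188 genes had opposite signs. Of all the genes called in both, 534 also passed for the interaction, and fold changes correlated across genes with r = 0.433. The 1338 genes of the same sign became 808 without Luc976 sample 1, 812 without Luc976 sample 3, 795 without shVHL61 sample 2 and 807 without shVHL61 sample 3. Their number was 2239 with length and GC trends removed and 2524 with the library set as a term. For the KIM-1 hairpin without and with shVHL61, 2253 genes were called with the same sign (1008 higher, 1245 lower, against 448 and 500.4 from independent lists) and 336 with opposite signs, with r = 0.313. With length and GC trends removed the same-sign number was 3649, and with the library set as a term 3526.

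The single hairpins against the same Luc976 samples shared 781 genes of the same sign (382 higher, 399 lower, against 152 and 223 from independent lists) and 280 of opposite sign. The counts from independent lists do not allow for the shared controls. The fold changes correlated with r = 0.304, and with a mean of 0.517 (0.397 to 0.648) in 20 simulations of unchanged groups against these controls. Fold changes of unchanged groups hold noise only, while real changes add variance. The 2 correlations are therefore not comparable and decide nothing about a shared effect. The covariance of the observed fold changes was 0.0504 against 0.0178 in the simulations. No library sets were simulated, and the sets are spread differently over Luc976 and the single hairpin groups. The excess was therefore not assigned to a shared effect. The simulations shared 0.15 calls on average and 1 at most, but unchanged groups give almost no calls to share. The 3 control samples cannot be split into parts of 2 or more, so how much of the overlap comes from them was not separated. Omitting 1 sample gave 474 (Luc976 sample 1), 427 (Luc976 sample 3), 502 (shVHL61 sample 2) or 497 (shVHL61 sample 3). The value was 1457 with length and GC trends removed and 1460 with the library set as a term. Against Luc976, 331 genes were higher in all 3 hairpin groups and 333 were lower.

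The authors' deposited table gives its own folds over Luc976. In the authors' deposited table VHL stands at 0.722 in shVHL61, 1.12 in shKIM1-A1 and 0.78 in shVHL61-KIM1A1 cells, and HAVCR1 at 1.20, 0.472 and 0.692. With a PPEE below 0.05, the authors' deposited table calls 1546, 2441 and 4748 genes in these comparisons, of which 1290, 2359 and 4663 also passed in edgeR, 0 of them with the opposite sign.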

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

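The tests on the VHL bound, on the median interaction as a sign of unlike action on HIF targets, and on the gap in length correlation within library sets were chosen only after the result was seen, as were the values on the log2(TPM + 1) scale. For 2800 genes the change with the KIM-1 hairpin differed with and without shVHL61 (edgeR, n = 3 per group), tested as an interaction. Across genes the interaction correlated with gene length at -0.374, and 2032 of the 2800 still passed with the length trend removed. With a single hairpin per gene, differences between lines and off-target effects were not separated from an interaction of the knockdowns. The interaction was positive for INHBB (log2 4.38), CA9 (3.10), IFITM2 (2.54) and CDA (2.43), and negative for SHC3 (-3.91), GPC4 (-3.03), FBN1 (-2.80) and FUT9 (-2.56). Among gene lists past the threshold, the median interaction was 0.41 for HIF targets, 0.30 for unfolded protein and amino acid stress, 0.27 for glycolysis, 0.22 for oxidative phosphorylation, 0.21 for IL-6/STAT3, 0.12 for cholesterol synthesis, 0.11 for lysosome genes, -0.07 for cell cycle and -0.20 for proximal tubule identity. On the log2(TPM + 1) scale, where the median of all genes was -0.135, these medians were, in the same order, 0.25, 0.14, 0.12, 0.06, 0.06, -0.03, -0.05, -0.22 and -0.38, so the cholesterol and lysosome lists turned negative. In other settings glycolysis stood at 0.16 with the library set as a term (0.13 and 0.19 within sets A and B), oxidative phosphorylation at 0.06 with the length trend removed, unfolded protein and amino acid stress at 0.18 with length and GC trends removed and proximal tubule identity at -0.37 with the set as a term (-0.21 and -0.76 within sets A and B). The calls for glycolysis, oxidative phosphorylation, IL-6/STAT3, cell cycle and lysosome genes ended with an estimated correlation.

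In 2 of 100 drawn assignments of the 12 samples to 4 groups of 3, the real one included, the interaction held as many genes. The draws mix the hairpin groups, which puts the differences between groups into the residual spread, and 92 of them gave 0 genes. They ask whether any group differs, not whether the hairpins interact, so they do not exclude chance for the interaction. The real assignment gave 2800 genes and the highest other 3370. That other draw sets the 6 libraries without the KIM-1 hairpin against the 6 with it, so it follows the study's own groups. For each of the 5 comparisons of 2 groups, 1 of the 10 splits of the 6 samples, the real one, gave as many genes. The real counts were 2374, 4456, 6059, 5975 and 7305 in the order of the report's figure of gene numbers, and the highest others were 3, 0, 0, 0 and 0. The other splits also mix the 2 groups, so a real difference enters the residual spread and low counts follow from that. With 10 splits no share under 0.05 can be had, and the splits decide nothing about chance.

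HIF targets did not pass with camera in shVHL61 cells against Luc976 (fry called them lower) and rose when the KIM-1 hairpin was added. A gene length and GC trend between libraries is argued against as the whole cause: with it removed the list median in shVHL61-KIM1A1 over shVHL61 was 0.65, against 0.60 before. A deeper VHL knockdown is argued against at the mRNA level, since the lower 95% bound of the VHL change was -0.026 and the upper bound 0.28. HAVCR1 mRNA did not fall more with shVHL61 than without it. Within library sets A and B the KIM-1 hairpin changed HAVCR1 by -0.80 and -0.59 with shVHL61, against -1.13 and -1.16 without. The HAVCR1 interaction did not pass. The same action of the KIM-1 hairpin with and without shVHL61 is argued against by the median interaction of 0.41 (0.25 on the log2(TPM + 1) scale). A hypothesis is that loss of KIM-1 raises HIF target transcription more where VHL is also lowered, which a second hairpin for each gene with VHL protein measured would test; differences between lines and off-target effects stay open until then.

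Genes higher with both hairpins tended to be short, with a correlation of fold change and length of -0.284 against shVHL61, -0.328 against shKIM1-A1 and -0.22 against Luc976. Within each library set the shVHL61-KIM1A1 libraries lay below all others, by 0.325 in set A and 0.198 in set B. A trend of single libraries is argued against for samples 2 and 3 of this group, which lie in set A. Set B holds its sample 1 alone (length correlation -0.04), near shKIM1-A1 sample 2 of set A (-0.029). The gap in set B therefore cannot separate the group from the library. A test drafted first, with all 12 libraries pooled, was met by a margin of only 0.011 and was replaced after its result was seen. Calls made only through the trend are argued against as the whole of the count, since 6073 genes passed against shVHL61 with the trend removed, of which 5082 were among the 6059. Whether the trend comes from the cells or from handling that differed by group cannot be told apart, because each group has its own libraries.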

How the results depend on the processing

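The trends on gene length and GC, the library set as a term and limma on log2(TPM + 1) were chosen only after the result was seen, and the other settings were planned. No named gene was reversed in the settings run. On the log2(TPM + 1) scale the medians of the cholesterol list for the interaction (0.12 to -0.03) and of the lysosome list for the interaction (0.11 to -0.05) and shVHL61-KIM1A1 against shKIM1-A1 (0.10 to -0.07) turned negative. The median of all genes also shifted on that scale, to -0.135 for the interaction and -0.153 for shVHL61-KIM1A1 against shKIM1-A1. These list medians stayed above it, so the change of sign is no reversal relative to all genes. For shKIM1-A1 against Luc976 the median of all genes was 0.087. The genes higher and lower on that scale went from 2109 and 2347 to 2917 and 1358 for shKIM1-A1 against Luc976, from 3002 and 2973 to 1264 and 5058 for shVHL61-KIM1A1 against shKIM1-A1, and from 1450 and 1350 to 711 and 2248 for the interaction. With the length trend alone removed, 2476 genes passed for the interaction. With length and GC trends removed, the genes changed rose to 3991 for shVHL61 against Luc976 and 4392 for the interaction, and the overlaps to 2239 (VHL hairpin without and with the KIM-1 hairpin), 3649 (KIM-1 hairpin without and with shVHL61) and 1457 (both against Luc976). With the library set as a term these values were 4117, 4799, 2524, 3526 and 1460. Omitting each sample in turn gave 1328 to 2484 genes for shVHL61 against Luc976, 1991 to 3517 for the interaction, and overlaps of 795 to 1422, 1785 to 2517 and 427 to 1150. It gave 3315 to 5189 genes for shKIM1-A1 against Luc976, 4897 to 5744, 4902 to 5768 and 6310 to 7064 for shVHL61-KIM1A1 against shVHL61, shKIM1-A1 and Luc976. Of the 114 list tests 42 passed, 12 with an estimated correlation and 87 with fry. With the length trend removed 30 passed, with length and GC trends removed 30, and with the library set as a term 43. The DESeq2 Wald test called 2375, 4178, 5687, 5626, 6940 and 2705 genes in the 6 comparisons, with 2168, 4056, 5569, 5503, 6812 and 2543 shared. A block on replicate number, which does not pair the samples, gave 1725 genes for shVHL61 against Luc976 and 2233 for the interaction. Of the 515 results on named genes, 515 stayed on the same side of the threshold with DESeq2 size factors, 510 with the Wald test (5 weaker), 506 with the block (9 weaker) 497 with the length trend removed (16 weaker, 2 stronger) and 501 with length and GC trends removed (9 weaker, 5 stronger). On the log2(TPM + 1) scale 485 did (19 weaker, 1 stronger), and over all omissions of 1 sample 3478 did (90 weaker, 2 stronger). A pseudocount was not varied, since counts were modelled.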

Other observations

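The pathway tests, the test of the OSM neighbours and the use of the IL-6/STAT3 list beside OSM were chosen only after the result was seen. The 298 KEGG pathway groups, which the deposited annotation gives by code and which are named here from general knowledge of those codes, were tested with camera like the gene lists, and none passed with an estimated correlation in any comparison. With the preset correlation, 0, 10, 7, 11, 7 and 10 groups passed in the 6 comparisons, in the order of the report's figure of gene numbers. Ribosome biogenesis genes fell with the KIM-1 hairpin, alone (1 rose and 36 fell of 69, adjusted p = 5.78e-09, and adjusted p = 0.357 with an estimated correlation) and with shVHL61 (1 rose and 38 fell, adjusted p = 3.78e-07, and adjusted p = 0.539 with an estimated correlation). The pathway passed in both with length and GC trends removed (adjusted p = 6.73e-10 and 2.83e-10). Ribosome genes were lower in shKIM1-A1 cells (2 rose and 53 fell of 131, adjusted p = 1.42e-07, and adjusted p = 0.828 with an estimated correlation). In shVHL61-KIM1A1 against shKIM1-A1 cells 88 rose and 1 fell (adjusted p = 5.16e-15, and adjusted p = 0.77 with an estimated correlation), but ribosomal protein genes are short and the adjusted p was 0.682 with both trends removed. Steroid biosynthesis (1 rose and 12 fell of 18, adjusted p = 0.0101) and TGF-beta signaling (9 rose and 31 fell of 69, adjusted p = 0.012) were lower in shKIM1-A1 cells, each with adjusted p = 0.357 with an estimated correlation. Complement and coagulation genes were also lower there (7 rose and 18 fell of 37, adjusted p = 0.0316, but 0.0811 with length and GC trends removed and adjusted p = 0.525 with an estimated correlation), with a positive interaction (16 positive and 5 negative, adjusted p = 0.00142, and adjusted p = 0.759 with an estimated correlation).

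OSM was counted in both lines that carry shVHL61 (507 and 716 counts) and hardly in the others (2 and 3). Activity of the whole gene neighbourhood is argued against, since the 4 nearest measured neighbours, LIF (0.02), GATSL3 (-0.35), TBC1D10A (-0.16) and MTMR3 (0.12), had a median of -0.067 in shVHL61 against Luc976. Whether the cells respond to oncostatin M was not decided, with an adjusted p of 0.493 for the IL-6/STAT3 list in shVHL61 cells. A hypothesis is that OSM may be induced by the lowered VHL level, but an effect of the hairpin on other targets, or of its insertion, stays open with 1 hairpin per gene. A second VHL hairpin, or VHL put back into these cells, would test it.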
